A study of Homo sapiens with 10 samples.

How the data were processed

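Compartment scores from Hi-C were analysed for 10 libraries of H9 cells: ESC, 24h and 48h with 2 libraries each, and definitive endoderm, pancreatic progenitor, polyhormonal and beta-like with 1 each. ESC replicate 1, made by the in-situ protocol with a 4 bp cutter, and ESC replicate 2, made with a 6 bp cutter, were treated as replicates of 1 group. The labels do not say that the libraries of a group come from separate cultures.

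Per the labels, the submitters' processing notes name Bowtie2 and HOMER, without versions or roles, and hg38. The authors deposited 1 table with a signed score per 50-kb bin and library, and its values show that every library was brought to 1 common distribution with median 0 (the largest difference between libraries in any percentile was 5.39e-05). How the score was computed, signed or smoothed is not stated. A score above 0 was read as compartment A and a score below 0 as compartment B. Since the distributions are the same in every library, a global gain or loss of A cannot be seen in them. Scores of adjacent bins correlated with r of 0.992 to 0.998, so neighbouring bins are not independent. The table holds no counts, so depth per library is unknown and no counting interval can be given. Only the 47369 bins scored in all 10 libraries were compared. 3648 bins were scored in no library. Chromosomes 4, 19, X and Y are not analysed here.

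Genes came from a GRCh38 table of 20052 protein-coding genes. It gives no strand, so the rule set before the data were examined, to place a gene by its transcription start site, was replaced by the bin of the gene's midpoint. 16027 genes fell in 12371 common bins. Genes placed by their start and by their end were run as alternatives added after the data were examined.

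The comparisons, tests, gene lists, naming rule and most alternative settings were fixed before the data were examined, except where the text says that one was added. For ESC, 24h and 48h, limma 3.58.1 in R 4.3.3 was fitted per bin to the 6 libraries, with lmFit and eBayes, no covariate, and a Benjamini-Hochberg adjusted p threshold of 0.05, two-sided. For each state, bins were counted whose score had the opposite sign in every library of the state and in both ESC libraries, a value with no p. As a background for these counts, unchanged libraries were simulated as the ESC mean plus or minus the difference between the libraries of the 24h or 48h group, scaled to 1 library, in 4 simulations for 1 library and 4 for a pair. The simulated libraries borrow their spread from 6 bp libraries. They are centred on the mean of the ESC libraries that they are then compared with. The error of that mean is left out, so this background may be too low. Overlaps of switched bins were set beside the product of both counts divided by the number of bins with the starting sign in both ESC libraries, and, for 2 states of 1 library each, beside the same simulation. For 24h and 48h, 2 unchanged groups of 2 libraries were simulated 200 times, each library the ESC mean plus or minus such a difference moved along the genome by a random distance, an alternative added after the data were examined. Adjacent switched bins were merged into domains.

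A further limma fit, added after the data were examined, compared the mean of the pancreatic progenitor, polyhormonal and beta-like libraries with ESC. It used all 10 libraries, took the spread from ESC, 24h and 48h alone (3 residual degrees of freedom), and assumed that the single libraries vary like the replicated groups. Both fits were tested on simulated data. With shifts of 0.5, 1 and 2 score units added to 200 bins each, the 24h fit recovered 29, 194 and 200, with 26 calls among the unshifted bins, and the pancreatic-stage fit 47, 196 and 200, with 37 such calls. All shifted bins were tested together, and adjustment is easier to pass when many bins shift, so these shares do not hold for a lone bin. No simulation was made for 48h.

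The 14 gene lists were pluripotency, primitive streak and mesendoderm, definitive endoderm, pancreatic progenitor, endocrine transcription factors, islet hormones and secretion, pancreatic exocrine, hepatocyte, intestine, neural ectoderm, mesoderm, housekeeping, olfactory receptors, and zinc fingers of chromosome 19. The exocrine, hepatocyte, intestine, neural and mesoderm lists stand for other cell types that the cultures could hold. The zinc finger list has no measured bin, since chromosome 19 is not analysed here, which leaves 13. Lists were tested with camera (limma), each bin once per list, with a preset correlation of 0.01 and adjustment over lists. For the single-library states the median difference of a list was placed among 10000 random lists of the same size, matched on decile of the ESC score. Such a percentile describes these libraries and is no test.

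Named genes followed a rule. From each list, up to 4 were named per comparison, the 2 with the largest increase and the 2 with the largest decrease. SOX2, NANOG, EOMES, SOX17, GATA4, GATA6, FOXA2, CXCR4, PDX1, PTF1A, NEUROG3, NEUROD1, INS and GCG were always followed, as were POU5F1 and MAFA, whose bins were not scored in all libraries, and NKX6-1, on a chromosome not analysed here. From the switched or called domains, the 10 per direction with the largest difference at their peak bin were taken, each named by the gene in that bin, with domains passed over where that bin holds no gene, and the 3 longest per direction were given by coordinates. Text names a part of these.

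The alternative settings fixed at that point were quantile normalization again, each library divided by its SD, the replicate number as a block, the cutter as a covariate, each library left out in turn, a margin on the difference of means (the SD of 0.29 between the ESC libraries), the ESC library of the same cutter alone, runs of at least 2 bins, chromosome medians set to 0, camera with an estimated correlation, and all bins scored in a library. The cutter as a covariate for the lists and every alternative of the added fit were chosen after the data were examined. Tables were handled with Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.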

Results

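The data are Hi-C compartment scores from H9 human embryonic stem cells (ESC, an established pluripotent line) carried toward the pancreatic lineage. Hi-C joins DNA ends that lie close together in the nucleus, and the compartment score separates each chromosome into an active, gene-rich A compartment (score above 0) and a less active B compartment (score below 0). There are 10 libraries in 7 groups. ESC, the 24h group and the 48h group (cells in Wnt and Activin A medium for 24 and 48 hours) have 2 libraries each. Definitive endoderm, pancreatic progenitor, polyhormonal and beta-like cells have 1 library each, so their values carry no replicate error. The deposited table covers 52502 bins of 50 kb on 20 chromosomes of hg38, of which 47369 (90.2%, 2368 Mb) were scored in all 10 libraries and were used for the comparisons. Chromosomes 4, 19, X and Y are not analysed here. The table gives no read counts, so the depth behind each score is unknown. The chromatin of ESC replicate 1 and of the 4 later states was digested with a 4 bp cutter, and that of ESC replicate 2 and of the 24h and 48h groups with a 6 bp cutter. The 4 later states were grown as suspension aggregates and the 24h and 48h groups as attached cells. Every library held 49.6 to 50.0% of the common bins above 0, a share that the normalization of the deposited scores sets, so only the place of A and B along the genome can differ between libraries.

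All 10 libraries shared 1 broad compartment map, and the pancreatic-stage libraries (pancreatic progenitor, polyhormonal and beta-like) lay farthest from ESC. Pearson's r across bins, which are not independent replicates, was 0.943 between the ESC libraries (Spearman's rho 0.938), 0.959 between the 24h libraries and 0.968 between the 48h libraries. The mean r with the ESC libraries was 0.950 at 24h, 0.947 at 48h, 0.936 for definitive endoderm, 0.885 for pancreatic progenitor, 0.887 for polyhormonal and 0.900 for beta-like. Polyhormonal and beta-like cells were the closest pair of single-library states, with r of 0.971. The lowest r between any libraries was 0.869, between 24h replicate 1 and pancreatic progenitor. On every chromosome every pair of libraries had a positive r, down to 0.595 on chromosome 22, so no chromosome had its score turned over. Chromosome 22 was also the least reproducible, with r of 0.844 between the ESC libraries, 0.833 within 24h and 0.811 within 48h. PITPNB, MPPED1, YWHAH, TCF20, TOM1, BPIFC, CLTCL1, GGT5, DGCR6L and WBP2NL, named below, lie on it. The ESC libraries, which differ in cutter, had opposite signs in 3556 bins (7.51%), the 24h libraries in 2759 and the 48h libraries in 2773.

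**Figure D1:**
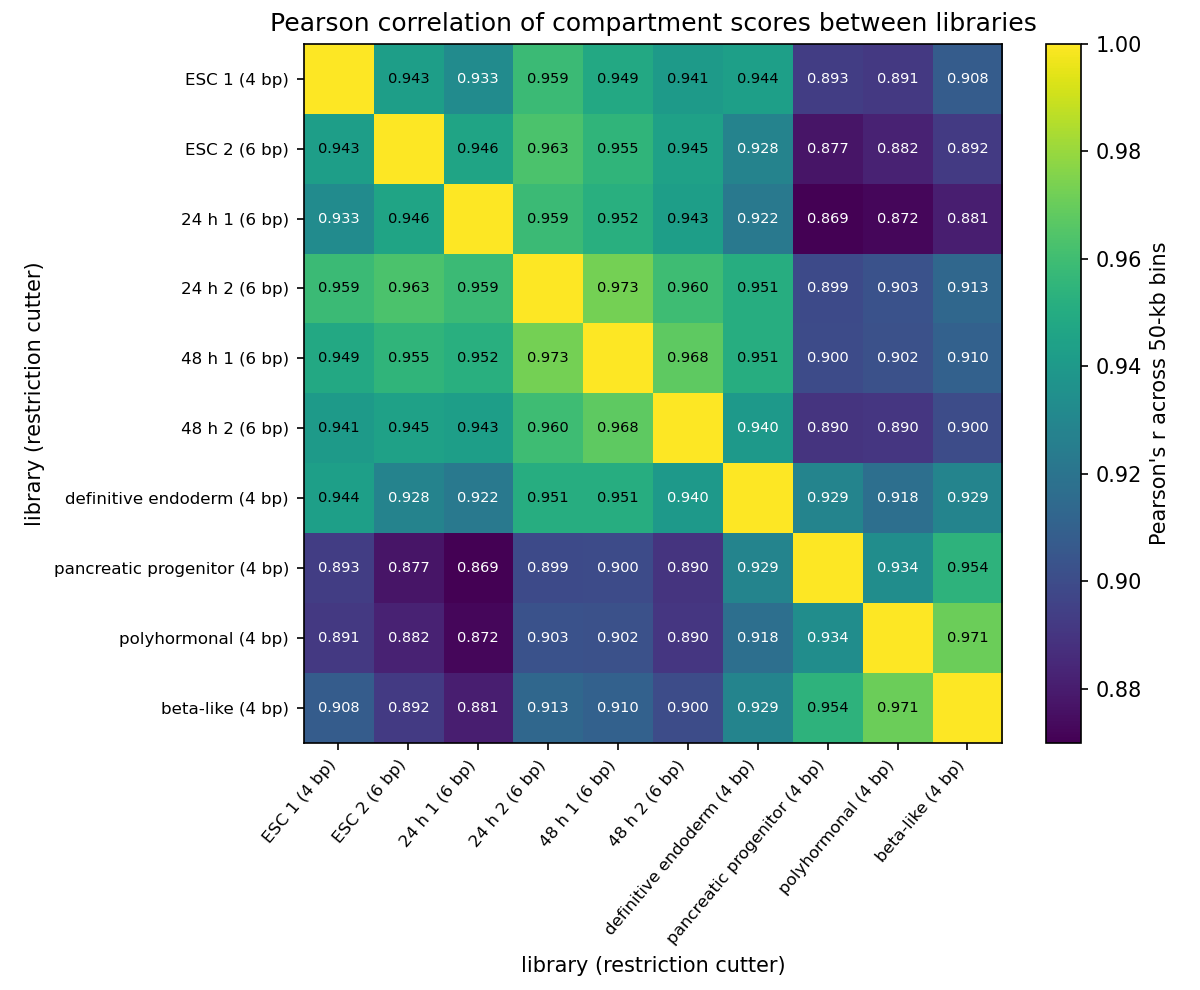
Pearson's r across 50-kb bins for each pair of the 10 libraries, with the restriction cutter of each library on both axes. The 6 libraries of ESC, 24h and 48h had r of 0.943 between the ESC libraries, 0.959 within 24h and 0.968 within 48h, and polyhormonal and beta-like reached 0.971.

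The first comparison asks which parts of the genome move between compartments in the first day of differentiation. At 24h, 345 bins lay in A that were in B in both ESC libraries, and 252 the reverse, together 597 bins (29.9 Mb, 1.26% of the common bins). The longest such B-to-A domain, 0.65 Mb on chromosome 5 from 158650001 to 159300000, held EBF1, a transcription factor best known from B cells, with RNF145 and UBLCP1, and its mean score was -0.26 in ESC and 0.32 at 24h. The longest A-to-B domain, 0.5 Mb on chromosome 13 from 73550001 to 74050000, held KLF12, a zinc-finger transcription factor, at 0.15 in ESC and -0.31 at 24h. Among genes in the bin of largest difference of a switched domain, PITPNB, a phosphatidylinositol transfer protein, had the largest difference upward, from -0.24 ± 0.32 in ESC to 0.57 ± 0.61 at 24h (SD, n = 2 each), with a wide spread at 24h. MPPED1 had the largest downward, from 0.33 ± 0.04 to -0.35 ± 0.45. PITPNB and MPPED1 lie on chromosome 22, the least reproducible, which had the largest share of switched bins at 24h (3.57%). ADCYAP1, the gene of the neuropeptide PACAP, went from 0.39 ± 0.06 to -0.19 ± 0.21, ERI2, an exonuclease, from -0.11 ± 0.09 to 0.43 ± 0.24, and YWHAH, a 14-3-3 protein, from 0.04 ± 0.01 to -0.43 ± 0.24. NINL, a centrosomal protein, went from 0.23 ± 0.07 to -0.17 ± 0.01, with little spread.

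None of the 14 lineage genes that were followed throughout lay in the opposite compartment to both ESC libraries at 24h. CXCR4, a chemokine receptor used as a surface marker of definitive endoderm, was at -0.01 ± 0.10 in ESC and 0.26 ± 0.17 at 24h. The switch rule could not be met by CXCR4 or SOX17 in any state, since their ESC libraries differ in sign. These were at -0.08 and 0.06 for CXCR4 and -0.07 and 0.04 for SOX17. EOMES, a transcription factor of the primitive streak, was at -0.22 ± 0.09 and -0.11 ± 0.05, and SOX2, a pluripotency factor, at -0.11 ± 0.09 and -0.33 ± 0.19. None of the 13 measured gene lists passed camera at 24h. The endoderm list had a median difference of -0.11 (15 bins, adjusted p = 0.602), with RSPO3, a Wnt-pathway secreted factor, lowest at -0.51 and HAS2, hyaluronan synthase, highest at 0.32. In the islet list SLC30A8, the zinc transporter of insulin granules, was the highest against ESC, at -0.74 ± 0.13 in ESC and -0.03 ± 0.00 at 24h. Median, mean and test did not all share a sign in the pluripotency, primitive streak, islet, exocrine, hepatocyte and intestine lists at 24h, in the endoderm and primitive streak lists at 48h, and in the neural, pancreatic progenitor and primitive streak lists between 24h and 48h. No bin passed limma at an adjusted p of 0.05 (3140 of 47369 bins had an unadjusted p below it). The switch count was 1506 without ESC replicate 1, 2177 without ESC replicate 2, 1128 without 24h replicate 1, 1757 without 24h replicate 2, and 371 when the means also had to differ by more than the spread between the ESC libraries. Simulated pairs of unchanged libraries gave 140 to 211 bins, a background that leaves out the error of the ESC mean and may be too low.

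The second comparison asks the same of the second day. At 48h, 471 bins lay in A that were in B in both ESC libraries, and 443 the reverse, together 914 bins (45.7 Mb, 1.93%). The longest B-to-A domain, 0.75 Mb on chromosome 11 from 128350001 to 129100000, held the ETS-family transcription factors ETS1 and FLI1, the potassium channels KCNJ1 and KCNJ5, and TP53AIP1, and its mean score was -0.21 in ESC and 0.26 at 48h. Another of 0.7 Mb on chromosome 5 from 96250001 to 96950000 held PCSK1, a prohormone convertase of endocrine cells, with CAST, ERAP1 and ERAP2, at -0.32 and 0.15. LMX1A, a LIM-homeobox transcription factor, was the only gene of a domain of 0.5 Mb on chromosome 1, at -0.27 and 0.25. COL5A2, a chain of type V collagen, had the largest difference upward of any gene at the peak bin of a domain, from -0.63 ± 0.07 in ESC to 0.05 ± 0.20 at 24h and 0.35 ± 0.23 at 48h (n = 2 each), and was at -0.75 in definitive endoderm. Musculin (MSC), a bHLH transcription factor, had the largest downward, from 0.64 ± 0.06 to 0.16 ± 0.22 and -0.32 ± 0.16.

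Other genes above 0 at 48h and below in ESC were RGS22, from -0.05 ± 0.07 in ESC to 0.56 ± 0.10, and SLF1, a DNA repair factor, from -0.22 ± 0.10 to 0.34 ± 0.01. With a wider spread in ESC, TMEM132E went from -0.47 ± 0.40 to 0.24 ± 0.03 and TRHR, the receptor of thyrotropin-releasing hormone, from -0.62 ± 0.32 to 0.04 ± 0.03. Genes below 0 at 48h and above in ESC were CXCL12, the ligand of CXCR4, from 0.29 ± 0.38 in ESC to -0.48 ± 0.07, NINL from 0.23 ± 0.07 to -0.43 ± 0.12 and TCF20 from 0.61 ± 0.47 to -0.24 ± 0.02. The spread in ESC was wide for CXCL12 and TCF20. CXCR4 itself was at 0.36 ± 0.03 (adjusted p = 0.447) and SOX17, a transcription factor of endoderm, at 0.21 ± 0.07, against -0.01 ± 0.08 in ESC (adjusted p = 0.592). PTF1A, a pancreatic transcription factor, crossed from -0.07 ± 0.04 to 0.08 ± 0.04. By limma no bin passed (4489 bins had an unadjusted p below 0.05). The switch count was 2013 without ESC replicate 1, 2445 without ESC replicate 2, 2087 without 48h replicate 1 and 1589 without 48h replicate 2.

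Of the gene lists, olfactory receptors and housekeeping genes scored lower at 48h than in ESC. The 217 bins of olfactory receptors, tissue-restricted genes in clusters that mostly lie in B, fell together, with a median difference of -0.16 and 170 of 217 bins below ESC (camera adjusted p = 9.31e-10). With an estimated correlation between bins that call was lost (adjusted p = 0.329). The 18 housekeeping bins also fell by a median of 0.18, with 15 of 18 below ESC (adjusted p = 0.00219), a call lost with an estimated correlation (adjusted p = 0.329) and with the cutter as a covariate (adjusted p = 0.0827). Their lowest members were SNRPD3, a spliceosome protein, at 0.84 ± 0.27 in ESC and 0.28 ± 0.07 at 48h, and POLR2A, the large subunit of RNA polymerase II, at 0.96 ± 0.24 and 0.50 ± 0.16. YWHAZ, another 14-3-3 protein, was the highest, at 1.51 ± 0.02 and 1.80 ± 0.54. The pluripotency list had 13 of 14 bins below ESC, with a median of -0.14 and adjusted p = 0.0925, but with the cutter as a covariate the median was 0.03 (adjusted p = 0.989). The other lists had adjusted p of 0.0710 or more, and no member of any list was called when adjusted over the list alone, at 24h or at 48h.

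Between the first and the second day, 340 bins went from B to A and 379 from A to B, in all 4 libraries concerned. Olfactory receptor bins fell from 24h to 48h, with a median difference of -0.11 (adjusted p = 5.55e-06), a call also lost with an estimated correlation (adjusted p = 0.564). No bin passed limma (3119 had an unadjusted p below 0.05). Of the 345 bins gone to A at 24h, 146 had also gone to A at 48h, where independent lists, which leave out the shared ESC libraries, would share 7.37 and simulated unchanged groups shared a mean of 5.47. For bins gone to B, 121 of 252 were shared, against 5.13 and 5.95. Part of the excess may come from the shared controls.

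**Figure D2:**
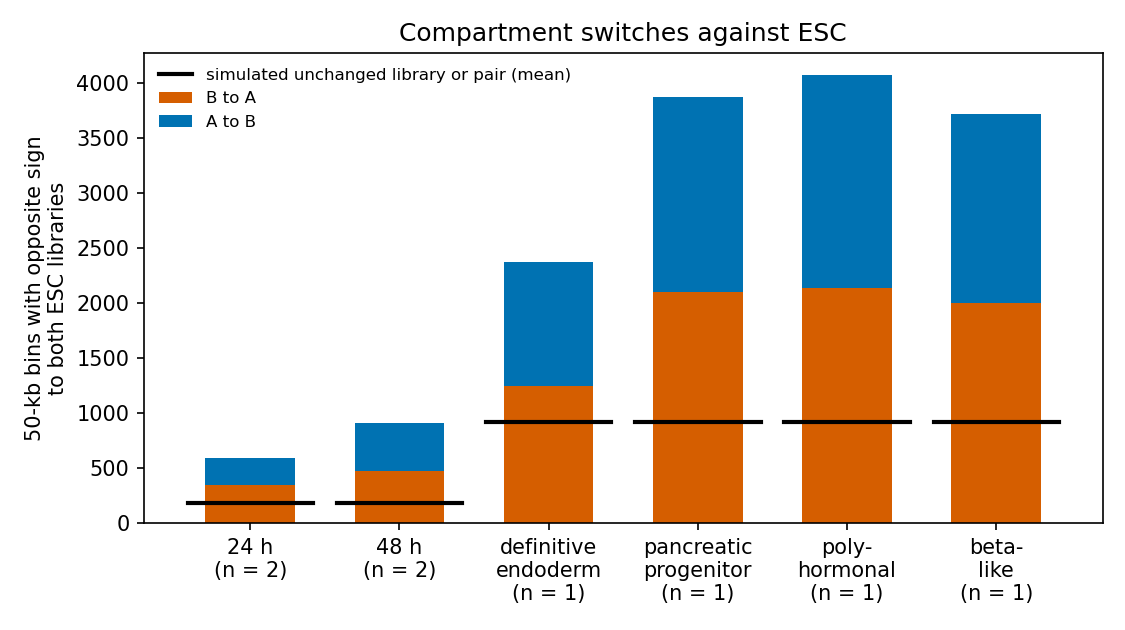
Number of 50-kb bins whose score has the opposite sign to both ESC libraries, per state, split into B to A and A to B, with black lines at the mean of simulated unchanged libraries (182.5 bins for a pair, 916.75 for 1 library). The lines leave out the error of the ESC mean and may be too low. The count is 597 at 24h, 914 at 48h and 2372 in definitive endoderm, and lies between 3719 and 4070 in the 3 pancreatic-stage libraries. A switch had to hold in 2 libraries at 24h and 48h but in 1 in the later states, so bar heights are not directly comparable. Single libraries gave 1128 and 1757 bins at 24h and 1589 and 2087 at 48h.

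Definitive endoderm, the germ layer that gives rise to pancreas and liver, was the state with FOXA2 in the A compartment. FOXA2, a pioneer transcription factor of endoderm (chromosome 20, bin 22550001 to 22600000), was at -0.63 ± 0.18 in ESC (SD, n = 2) and 0.31 in definitive endoderm, and was below 0 in the 9 other libraries. HAS2 went from -0.71 ± 0.16 to 0.22, SOX17 from -0.01 ± 0.08 to 0.30 and CXCR4 from -0.01 ± 0.10 to 0.67. In total 1246 bins lay in A that were in B in both ESC libraries and 1126 the reverse, together 2372 bins (119 Mb, 5.01%), where simulated single unchanged libraries gave 787 to 1032. That background may be too low, as it leaves out the error of the ESC mean. Counts at 24h and 48h asked for 2 libraries, so they are not directly comparable with this one. Taken singly, 24h libraries gave 1128 and 1757 bins and 48h libraries 1589 and 2087. The ETS1 and FLI1 domain spanned 2.2 Mb on chromosome 11 from 126900001 to 129100000, at -0.42 in ESC and 0.41 in definitive endoderm. Its length is not directly comparable with that at 48h, where a switch had to hold in 2 libraries.

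EPHA4, an ephrin receptor, lay in a B-to-A domain of 1.85 Mb on chromosome 2 from 220200001 to 222050000, at -0.25 and 0.30. DUSP10, a MAP kinase phosphatase, lay with HHIPL2 and TAF1A in a domain of 1.45 Mb on chromosome 1 from 221150001 to 222600000, at -0.75 and 0.17. The longest A-to-B domain, 1.6 Mb on chromosome 5 from 44150001 to 45750000, held FGF10, a growth factor of organ mesenchyme, with MRPS30, at 0.13 and -0.31. PIK3R1, the regulatory subunit of phosphoinositide 3-kinase, lay in another of 1.35 Mb on chromosome 5, at 0.31 and -0.24, and 16 genes, among them BOC, BTLA and CD200, in one of 1.5 Mb on chromosome 3, at 0.32 and -0.20. Among genes at the peak bin of a switched domain, KEL, the Kell blood group metalloprotease, had the largest difference upward, from -0.40 ± 0.04 to 0.68, followed by TOM1, an endosomal sorting protein, from -0.81 ± 0.13 to 0.11, BPIFC from -0.86 ± 0.12 to 0.03 and PMP2, a myelin lipid carrier, from -0.30 ± 0.14 to 0.58. RRS1, a ribosome assembly factor, had the largest downward, from 0.79 ± 0.27 to -0.01, followed by CLEC2B, a C-type lectin, from 0.48 ± 0.15 to -0.31 and PRRC2C from 0.01 ± 0.01 to -0.76.

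The fixed endoderm list had 12 of 15 bins above ESC, with a median difference of 0.13, at percentile 95.67 of 10000 random lists matched on the ESC score. FOXA2, HAS2 and FRZB, a secreted Wnt antagonist, crossed into A. FOXA1, a paralog of FOXA2, stayed in B, at -0.90. The neural ectoderm list had a median of -0.13 (percentile 0.52), with POU3F3, a POU-domain transcription factor of brain, crossing into B at -0.47. The percentile describes these libraries and is no test. Without ESC replicate 1 the switch count was 4244 and without ESC replicate 2 it was 4057.

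**Figure D3:**
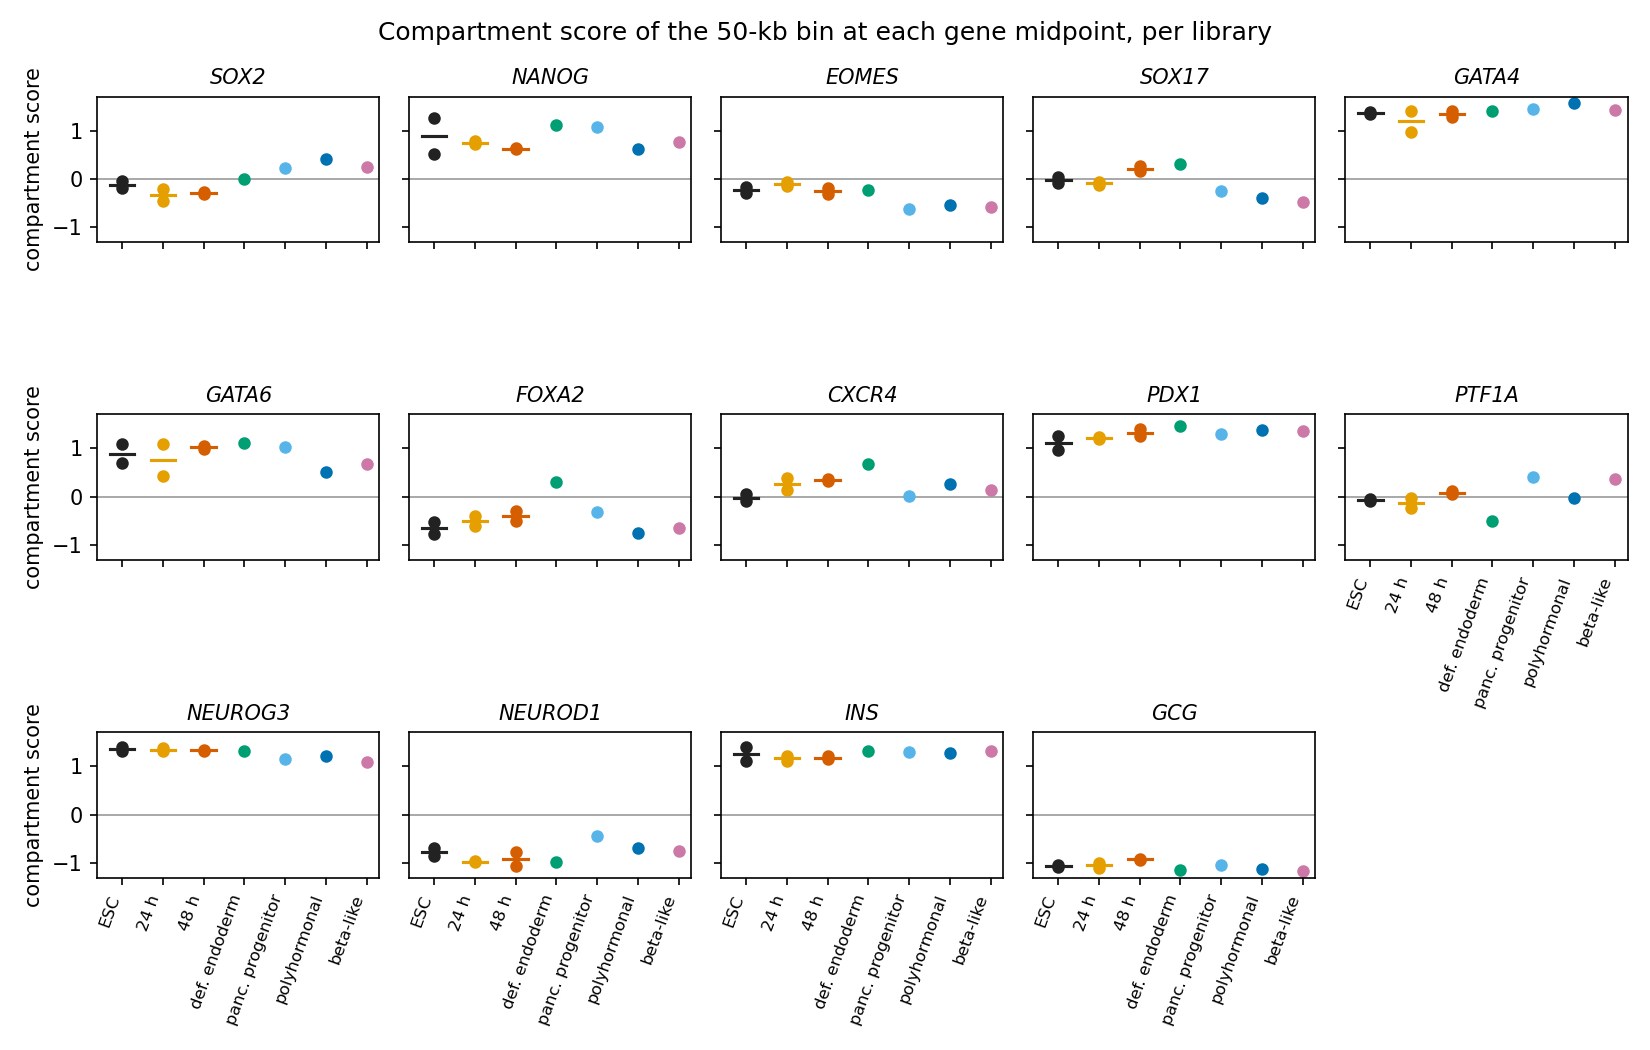
Compartment score (vertical axis, no unit) of the 50-kb bin at the midpoint of 14 lineage genes in each of the 10 libraries, 1 dot per library, with a bar at the mean where there are 2. FOXA2 is above 0 in definitive endoderm, at 0.31, SOX2 in the 3 pancreatic-stage libraries, at 0.23, 0.42 and 0.25, and GCG stays below -0.90 in every library.

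Pancreatic progenitor cells, the stage that gives rise to the cells of the pancreas, carried the longest blocks of newly active compartment. A block of 4.65 Mb on chromosome 9 from 80800001 to 85450000, with TLE1, a corepressor of Notch and Wnt signalling, RASEF and NTRK2, the receptor of brain-derived neurotrophic factor, had a mean of -0.76 in ESC and 0.57 in this state. A block of 3.55 Mb on chromosome 2 from 3750001 to 7300000, with SOX11, a transcription factor of embryonic development, stood at -0.51 and 0.63. A block of 3.0 Mb on chromosome 5 from 143000001 to 146000000, with NR3C1, the glucocorticoid receptor, stood at -0.87 and 0.49. PTF1A, required for pancreas formation, went from -0.07 ± 0.04 in ESC and -0.50 in definitive endoderm to 0.42. In total 2103 bins went to A and 1770 to B, together 3873 (194 Mb, 8.18%).

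Other genes entering A were ID4, an inhibitor of bHLH factors, at -0.69 ± 0.29 in ESC and 0.32, EPM2A, the phosphatase laforin, at -0.69 ± 0.31 and 0.32, CHD9, a chromatin remodeler, at -0.68 ± 0.10 and 0.33, and MECOM, a zinc-finger transcription factor, at -0.67 ± 0.33 and 0.06. Genes entering B were CLTCL1, a clathrin heavy chain, at 0.76 ± 0.65 and -0.62, GGT5 at 1.03 ± 0.39 and -0.33, DGCR6L at 0.95 ± 0.52 and -0.40, CEBPD, a stress-induced transcription factor, at 1.07 ± 0.36 and -0.17, and ENPP3, an ectonucleotide pyrophosphatase, at 1.16 ± 0.16 and -0.02. CLTCL1, GGT5 and DGCR6L lie on chromosome 22, the least reproducible, and have a wide spread in ESC. The block with FGF10 on chromosome 5 stood lower than in definitive endoderm, at -0.80. The fixed pancreatic progenitor list had 12 of 15 bins above ESC, with a median of 0.13 (percentile 95.52). PTF1A and HNF4G, a nuclear receptor at -1.12 ± 0.05 and -0.70, had the largest increases in it, and NKX6-2, a homeobox factor, the largest decrease, from 1.24 ± 0.12 to 0.45. The neural list had a median of -0.25 (percentile 0.21), with OTX1 at 0.24 ± 0.35 in ESC and -0.66. Against definitive endoderm, 2352 bins went to A and 2165 to B, together 4517, above the 2759 to 3556 bins of opposite sign between libraries of 1 replicated group.

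Polyhormonal cells, endocrine cells that express more than 1 islet hormone, had 2142 bins in A that were in B in both ESC libraries and 1928 the reverse, together 4070 (203.5 Mb, 8.59%). At the peak bins of switched domains, the largest entries into A were C1orf87, from -1.07 ± 0.00 to 0.21, in a block of 2.45 Mb on chromosome 1 from 59250001 to 61700000 that also held NFIA, a transcription factor of glia, and HOOK1, then APOB, the protein of low-density lipoprotein, from -0.86 ± 0.07 to 0.41, and PCP4, a calmodulin-binding peptide, from -0.31 ± 0.05 to 0.81. INSM1, a zinc-finger factor of endocrine cells, crossed from -0.41 ± 0.08 to 0.09, and SCG2, a secretory granule protein, from -0.18 ± 0.15 to 0.30. The largest entries into B at such bins were ENPP3 at -0.55, PEX7, a peroxisomal import receptor, from 1.05 ± 0.35 to -0.38, MSC at -0.65 and PHACTR2 from 0.96 ± 0.14 to -0.30. PRDM1, a transcriptional repressor, crossed from 1.13 ± 0.24 to -0.16, and G6PC2, an islet glucose-6-phosphatase, from 0.58 ± 0.31 to -0.25. The islet hormone and secretion list had a median of -0.04 (percentile 40.3) and the endocrine transcription factor list of -0.03 (percentile 59.5), with a mean just above 0. Against pancreatic progenitor, 2067 bins went to A and 2151 to B.

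Beta-like cells, made to resemble the insulin cells of the islet, had 2006 bins in A that were in B in both ESC libraries and 1713 the reverse, together 3719 (186 Mb, 7.85%). Among genes at the peak bin of a switched domain, ZFHX4, a zinc-finger homeobox factor, had the largest difference upward, from -0.98 ± 0.03 in ESC to 0.18, followed by HOOK1, a microtubule adaptor, from -0.91 ± 0.03 to 0.18 and APOB at 0.07. Genes at such bins that entered B included ENPP3 at -0.41, ELOC, elongin C, from 1.08 ± 0.23 to -0.36, CEBPD at -0.23, SGMS1, a sphingomyelin synthase, from 0.23 ± 0.28 to -1.02, and MCM4, a subunit of the replicative helicase, from 1.07 ± 0.34 to -0.02. INS, the insulin gene, was in A in every library, at 1.25 ± 0.19 in ESC and 1.32 in beta-like cells, and so was PDX1, the pancreatic homeobox factor, at 1.11 ± 0.20 and 1.37. GCG, the glucagon gene, was in B in every library, at -1.06 ± 0.02 and -1.17. NEUROG3, the factor that starts endocrine differentiation, was at 1.35 ± 0.06 and 1.09, and NEUROD1, its target, at -0.77 ± 0.11 and -0.75. SCG2 at 0.31 and UCN3, a peptide of mature beta cells, at 0.03 ± 0.06 in ESC and 0.49, had the largest increases in the islet list, and TTR, the thyroxine carrier transthyretin, at -0.51, and G6PC2, at -0.05, the largest decreases. The islet list had a median of 0.03 (percentile 83.1), with a mean just below 0, and the endocrine list of -0.14 (percentile 15.9). Against polyhormonal, 1402 bins went to A and 1332 to B, fewer than the 2759 to 3556 bins of opposite sign between libraries of 1 replicated group.

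The pancreatic-stage libraries shared much of their switched territory. 992 bins (49.6 Mb) were in A and 982 (49.1 Mb) in B in all 3 of them, against both ESC libraries. Of these, 435 (43.9%) and 506 (51.5%) had the same switch in definitive endoderm, 123 (12.4%) and 203 (20.7%) at 48h, and 107 (10.8%) and 122 (12.4%) at 24h. A switch had to hold in 2 libraries at 24h and 48h but in 1 in definitive endoderm, so these shares are not directly comparable. The B-to-A block with SOX11 and the A-to-B block with FGF10 had the same boundaries in all 3, and so did an A-to-B block of 1.6 Mb on chromosome 9 from 5450001 to 7050000 in polyhormonal, beta-like and pancreatic progenitor cells, with CD274, the immune ligand PD-L1, and GLDC, glycine decarboxylase, at 0.46 in ESC and between -0.52 and -0.33. A switched block can reach only as far as both ESC libraries keep the starting sign. Shared boundaries may therefore be set by ESC and are no measure of agreement between the states. Polyhormonal and beta-like cells shared 1490 bins gone to A (195 for independent lists, 98.5 for simulated unchanged pairs) and 1325 gone to B (152 and 84.0). Definitive endoderm and pancreatic progenitor shared 661 (119 and 98.5) and 697 (91.6 and 84.0). Part of the excess may come from the shared controls.

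To ask which bins of the pancreatic-stage libraries differed from ESC on average, their mean was compared with ESC in a limma fit of all 10 libraries. A mean can pass where not every one of these libraries moved. This fit was added after the data were examined, and it assumes that each lone library varies like the replicated groups. 2939 bins rose, by a median of 0.67, and 2496 fell, with a median difference of -0.64. Of the bins that rose, 1144 (38.9%) crossed into A, and of those that fell 905 (36.3%) crossed into B. The bins that rose had a median of 2 genes within 0.5 Mb, the same as all bins below 0 in ESC, and those that fell had 6, against 8 around all bins above 0 in ESC. These sets are unlike, since some bins that fell were below 0 in ESC. Their median ESC score was 0.38, against 0.87 in all bins above 0, so the gene counts are not directly comparable. The longest domain that rose was 7.25 Mb on chromosome 9 from 78250001 to 85500000, with TLE4, TLE1, RASEF and NTRK2 among its 19 genes, from -0.86 in ESC to 0.27. There NTRK2, chosen like RASEF after its values were seen, rose by 1.39 ± 0.17 (SE, adjusted p = 0.0107) and RASEF by 1.21 ± 0.09 (adjusted p = 0.00943). Definitive endoderm was still below 0 for them, at -0.18 and -0.90, but above the ESC means of -0.55 ± 0.37 and -1.07 ± 0.04. Domains of 5.6 Mb on chromosome 2, with SOX11 and ID2, an inhibitor of bHLH factors, and of 3.25 Mb on chromosome 9, with TLR4, the receptor of bacterial lipopolysaccharide, followed. The longest domains that fell were 2.5 Mb on chromosome 8 from 71550001 to 74050000, with MSC, the ion channel TRPA1 and TERF1, a telomere protein, from 0.68 to -0.35, then 2.45 Mb on chromosome 6, with IFNGR1, TNFAIP3 and PEX7, and 2.1 Mb on chromosome 16, with SIAH1 and ORC6.

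Of the genes at the peak bins of called domains, APOB rose by 1.01 ± 0.19 (adjusted p = 0.0246), ZFHX4 by 0.94 ± 0.10 (adjusted p = 0.00943) and CHD9 by 0.90 ± 0.12 (adjusted p = 0.0122). WBP2NL, ADRA1A, an adrenergic receptor, DACH1, a transcription cofactor, MRPS6, PIWIL1, a germline argonaute protein, TOM1 and UBLCP1 rose by 0.74 to 1.01, of which WBP2NL, at 1.01, was at 0.63 without ESC replicate 2 and 1.39 without ESC replicate 1. ENPP3 changed by -1.49 ± 0.12 (adjusted p = 0.00943), CEBPD by -1.26 ± 0.17 (adjusted p = 0.0130) and TGM1, a transglutaminase of skin, by -1.05 ± 0.12 (adjusted p = 0.010). The domain with ENPP3 was not lower in the pancreatic-stage libraries alone. Its olfactory receptor bin, on chromosome 6 from 131700001 to 131750000, differed from ESC by -0.68 at 48h, -1.17 in definitive endoderm and -1.14 in pancreatic progenitor. DGCR6L, IL20RA, a cytokine receptor, GPATCH11, CYP2C18, a cytochrome P450, TMED5, LYN, a Src-family kinase, and DSEL changed by -0.90 to -1.05. With the cutter as a covariate, which compares the pancreatic-stage libraries with the 4 bp ESC library alone, 1616 bins were called, 1330 of them shared with the 5435, and ZFHX4, ENPP3, CEBPD, TGM1, DGCR6L (at -0.68, from -1.05) and TMED5 kept their call while the other 14 of these 20 genes lost it, as NTRK2 and RASEF kept theirs (adjusted p = 0.0422 for both). The count was 2780 without ESC replicate 1, 1616 without ESC replicate 2, 3366 without 24h replicate 1 and also without 24h replicate 2, and 2570 without 48h replicate 1 and also without 48h replicate 2. The p-values rest on the spread within ESC, 24h and 48h alone, which may be technical. The spread among the pancreatic-stage libraries does not enter them.

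**Figure D4:**
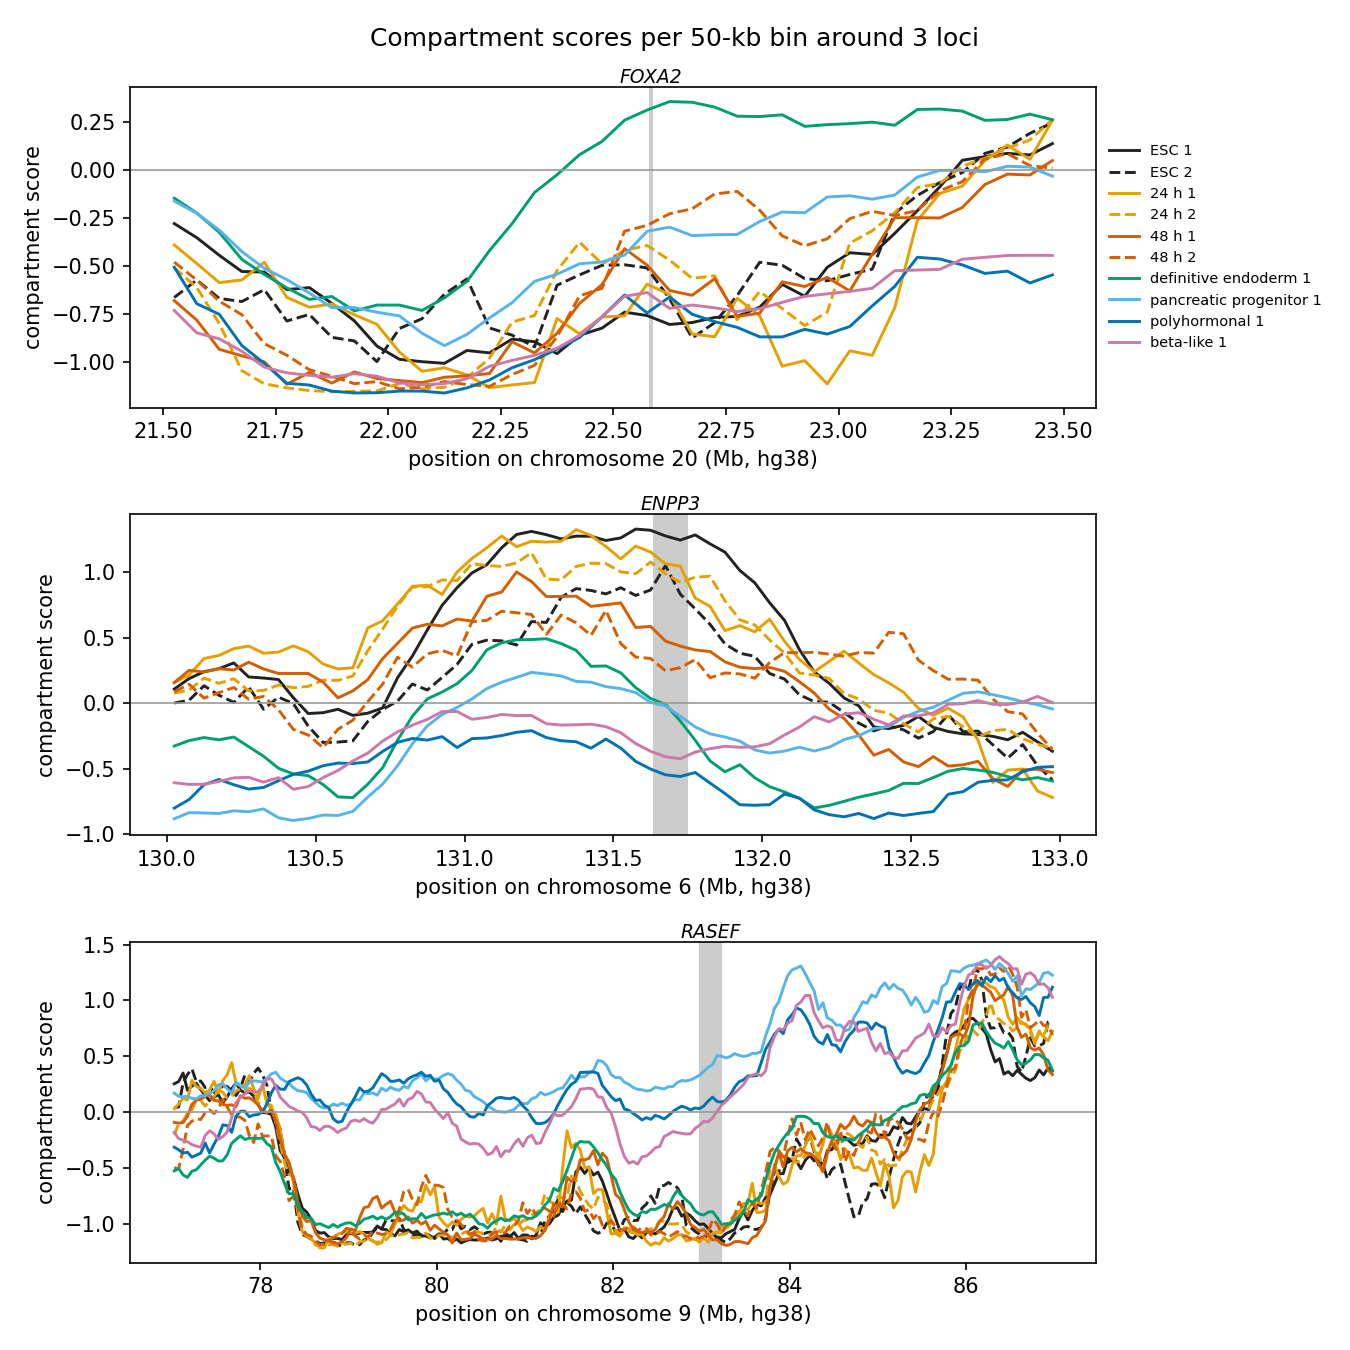
Compartment score (vertical axis, no unit) of each 50-kb bin along 3 loci (horizontal axis, position in Mb on hg38), 1 line per library, with the named gene shaded. Definitive endoderm alone is above 0 at FOXA2 (0.31), ENPP3 goes from 1.16 in ESC to -0.55 in polyhormonal cells, and the 3 pancreatic-stage libraries leave the other 7 across the 7.25 Mb domain with RASEF. In the domain with ENPP3, the olfactory receptor bin was already -1.17 from ESC in definitive endoderm.

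In this fit the gene lists moved little as groups, apart from the olfactory receptors, whose median difference was -0.23 over 217 bins (camera adjusted p = 8.31e-08). That call was lost with an estimated correlation (adjusted p = 0.862) and held with the cutter as a covariate (adjusted p = 5.71e-06). Of these bins 29 fell and none rose, and adjusted over the list alone 39 fell and 1 rose, while with the cutter as a covariate only 3 fell, or 1 adjusted over the list alone. In the pluripotency list, with a median of -0.14 (-0.34 with the cutter as a covariate, adjusted p = 0.0702), FOXD3 fell by 0.59 ± 0.12 (adjusted p = 0.0283), while SOX2 was 0.41 ± 0.12 above ESC (adjusted p = 0.0693) and crossed into A in all 3 libraries. In the primitive streak list, 2 bins rose: EVX1, a homeobox factor, by 0.60 ± 0.12 (adjusted p = 0.0281) and TBXT, brachyury, by 0.40 ± 0.09 (adjusted p = 0.0461). TBXT was 0.755 above ESC in polyhormonal cells, so its mean rests largely on that library. The median of the primitive streak list, -0.09, and its mean, 0.02, differ in sign. In the endoderm list, with a median of -0.03, PRDM1 changed by -0.74 ± 0.15 (adjusted p = 0.0327) and HHEX, an early factor of liver and pancreas, by -0.62 ± 0.14 (adjusted p = 0.0363), and adjusted over the list alone 1 bin rose and 5 fell. The PRDM1 difference was uneven, at -1.28 in polyhormonal and -0.77 in beta-like cells. SOX17 was at -0.26, -0.38 and -0.48 in the 3 libraries and EOMES at -0.62, -0.53 and -0.58.

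In the pancreatic progenitor list, with a median of 0.06, HNF4G rose by 0.58 ± 0.11 (adjusted p = 0.0236) and NKX6-2 changed by -0.55 ± 0.10 (adjusted p = 0.0230), and adjusted over the list alone 2 bins rose and 1 fell. SOX9, a factor of progenitors and ducts, was 0.37 ± 0.09 above ESC (adjusted p = 0.0520). No bin of the endocrine transcription factor list (median -0.05), the islet list (0.01), the exocrine list (0.10), the intestine list (-0.08) or the mesoderm list (0.05) was called, over all bins or adjusted over the list alone. In the hepatocyte list, whose median of -0.01 and mean of 0.15 differ in sign, APOB rose, as given above, and in the neural list (-0.08) PAX3, a factor of neural crest, rose by 0.71 ± 0.11 (adjusted p = 0.0171). In the housekeeping list (-0.05) SNRPD3 fell from 0.84 ± 0.27 to -0.16 ± 0.16 (mean ± SD, adjusted p = 0.0173). For the pluripotency, primitive streak, hepatocyte, neural and housekeeping lists the count adjusted over the list alone was the same as over all bins. The 10 list members named here as passing the test lost their call with the cutter as a covariate (adjusted p of 0.0637 to 0.132), and the lists other than the olfactory receptors had camera adjusted p of 0.741 to 0.865. NANOG, GATA4 and GATA6 were in A in every library, between 0.42 and 1.57.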

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

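The tests of the cutter as a cause, for the olfactory receptors and for every pancreatic-stage bin, were chosen only after the result was seen, and the pancreatic-stage fit was itself added after the data were examined.

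Olfactory receptor bins scored lower at 48h than in ESC, and also lower at 48h than at 24h, with a median difference of -0.11 (217 bins, camera adjusted p = 5.55e-06, and 0.564 with an estimated correlation), a difference between the 24h and 48h responses that was tested directly. Against the ESC library of the same cutter alone the 48h median was still -0.15, below all 10000 matched random lists. The fall is thus also seen where the cutter is the same. The random lists are scattered bins while receptor bins lie in clusters, so their range is too narrow. Since 1 ESC library is compared, its own deviation is not excluded. With 1 median per cluster, 75.9% of the 29 receptor clusters lay below ESC at 48h, against 51.7% in matched random sets (percentile 99.31), which argues against a few large clusters. A shift of closed, gene-poor sequence in general was not separated from one of receptor genes, and depth, which is unknown, stays open. In definitive endoderm, which differs from 48h in cutter and culture format, only 48.3% of the clusters lay below ESC (percentile 31.64), and the 48h call is lost with an estimated correlation, so whether receptor regions change with endoderm induction stays open.

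VCP, a housekeeping gene coding for a protein-unfolding ATPase, was above both ESC libraries in both 24h libraries and below both in both 48h libraries, with means of 1.21 ± 0.01 in ESC, 1.25 ± 0.02 at 24h and 0.97 ± 0.28 at 48h (SD, n = 2 each), a difference of -0.28 between 48h and 24h, a comparison in which no bin passed limma (smallest adjusted p = 0.746).

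The pancreatic-stage change against ESC in 5435 bins mixes the lineage with the cutter and the culture format. The cutter cannot be the cause of every bin, since 1330 bins kept their call and direction with the cutter as a covariate. In 2780 bins called without the 4 bp ESC library, that library lay at 0.26 on a scale with the 6 bp ESC library at 0 and the pancreatic-stage mean at 1, above 0.5 on 3 of 20 chromosomes, so for the remaining bins the cutter and the state cannot be told apart. The spread of a single pancreatic-stage library is argued against: each, left out in turn, lay at 0.84 (pancreatic progenitor), 0.92 (polyhormonal) or 0.90 (beta-like) of the way from ESC to the other pair in bins called without it, and above 0.5 on all 20 chromosomes. The same ESC libraries called the bins and set 0, so error in the ESC mean also moves these positions toward 1 and is not excluded. For reference, the 24h mean lay at 0.11 and the 48h mean at 0.17 in the 5435 bins. Definitive endoderm, also grown as aggregates, lay at 0.42 in these bins, above 0.5 on 8 of 20 chromosomes, so culture format stays open, as does the pancreatic fate itself, which the design confounds with both.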

How the results depend on the processing

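All alternatives of the pancreatic-stage fit, the cutter as a covariate for the lists, genes placed by start or end, and runs of bins for successive states were chosen only after the data were seen. Switch counts moved beyond 1.5 times where fewer libraries had to share the sign: with the same-cutter ESC library alone they were 1506 at 24h, 2013 at 48h and 4057 in definitive endoderm, and with 1 library left out they ranged from 1128 to 2177, 1589 to 2445 and 4057 to 4244, since the rule then asks for fewer signs. The margin gave 371 at 24h, as its construction removes small differences. Quantile normalization, chromosome medians at 0 and runs of at least 2 bins stayed within 1.5 times for every state, as did every alternative for pancreatic progenitor, polyhormonal and beta-like. The limma count for 24h, 48h and their difference was 0 in each alternative run, with 1423 to 5845 bins at an unadjusted p below 0.05. Replicate numbers did not pair libraries (correlations of -0.0856, -0.0331 and -0.0532). The pancreatic-stage count was 1616 with the cutter as a covariate, 1757 with the replicate block and 1616 to 4346 with 1 library left out, and the fewer residual degrees of freedom of most of these (2 against 3) are part of their construction. The count of lists called at 24h and 48h, 2, was 0 with an estimated correlation and 1 with the cutter as a covariate, and for the pancreatic-stage fit, 1, it was 0 with an estimated correlation; the cause was not tested. The range between libraries in the share of bins in A, 0.43 percentage points, was 0.00103 over all bins scored in a library, as the normalization fixes it. Of the 20 genes named from the pancreatic-stage fit, CEBPD, ENPP3, TGM1, TMED5 and ZFHX4 kept their call in every alternative and 14 lost it with the cutter as a covariate. None of these 20 genes, and no list that passed camera, turned its direction, but some differences that passed no test did, such as NANOG in the pancreatic-stage fit (-0.07, and 0.30 without ESC replicate 1) and the mean of the pluripotency list at 24h (-0.02, and 0.11 with the cutter as a covariate). Autosomes only was not run, since the table holds no other chromosome. Depth limits are unknown.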

Other observations

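The tests of gene families and of further genes in this part were all chosen only after the data were seen.

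Secreted ribonuclease genes fell together in the pancreatic-stage libraries. Among 270 families of genes sharing a symbol prefix, the RNASE family, whose 9 bins lie in 1 cluster on chromosome 14, had a median difference from ESC of -0.68, with 8 bins called lower and none higher (camera adjusted p = 3.4e-06, and 1.76e-05 with the cutter as a covariate). With an estimated correlation the adjusted p was 0.926. An olfactory receptor cluster on chromosome 14, from 19700001 to 22650000, also fell, with a median difference of -0.48. Whether the ribonuclease bins moved apart from a shift of their region was not tested. RNASE7, an antimicrobial ribonuclease of skin, went from 1.08 ± 0.08 in ESC (SD, n = 2) to 0.35 ± 0.04 in the 3 pancreatic-stage libraries, and RNASE1, the pancreatic-type ribonuclease, from 0.89 ± 0.00 to 0.20 ± 0.06. In this paragraph the SD of the pancreatic-stage libraries is a spread between 3 states of 1 library each, not between replicates. The cystatins (CST, cysteine protease inhibitors, mostly in 1 cluster on chromosome 20) had a median of -0.47, with 4 of 9 bins called lower (adjusted p = 0.0126, and 0.926 with an estimated correlation). CST3, cystatin C, went from 0.17 ± 0.01 to -0.38 ± 0.40. Genes named CD, surface antigens spread over many chromosomes, had a median of -0.19 over 73 bins with 9 called lower (adjusted p = 0.0170, and 0.926 with an estimated correlation), among them CD84 and CD48, immune receptors near each other on chromosome 1, at -0.81 ± 0.09 and -0.78 ± 0.10 from ESC (difference ± SE), and CD274 at -0.92 ± 0.10, all 3 also called with the cutter as a covariate. AKR, the aldo-keto reductases, had a median of 0.32 over 13 bins (adjusted p = 0.121) that became 0.54 with the cutter as a covariate (adjusted p = 7.29e-04), with AKR1C3, a steroid-converting enzyme, at -0.32 ± 0.34 in ESC and 0.16 ± 0.08, which was called with that covariate alone (adjusted p = 0.0451, and 0.0901 without it). An estimated correlation was not run together with that covariate, so the AKR call was not checked in this way.

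Some lineage genes lie in bins scored by the 4 bp libraries alone. POU5F1, the pluripotency factor OCT4, was in A in each of these, at 0.90 in ESC, 1.24 in definitive endoderm, 1.21 in pancreatic progenitor, 1.34 in polyhormonal and 1.28 in beta-like cells. SCG5, a secretory granule chaperone, was at 0.40 in ESC and below 0 in the 4 others, from -0.34 to -0.07. PRSS1, trypsinogen, was at -0.33 in ESC, 0.73 in definitive endoderm, 0.13 in pancreatic progenitor, -0.35 in polyhormonal and -0.49 in beta-like cells. MAFA, a factor of mature beta cells, was also scored in ESC replicate 2 and 1 library of 48h, and was at 1.38 and 0.91 in ESC, 0.19 at 48h and 1.41 in beta-like cells. In all, 943 bins were scored in every 4 bp library and in no 6 bp library, of which 67.8% lay in A in ESC replicate 1, and 38 bins the reverse. EBF1, in the first day's longest B-to-A domain, was at -0.25 ± 0.01 in ESC, 0.34 ± 0.20 at 24h, -0.22 ± 0.22 at 48h and between 0.61 and 0.75 in the 4 later states.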
